A study of Mus musculus with 16 samples.

How the data were processed

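RNA from 4 mouse tumour organoid lines in 2 media each was sequenced in 2 pools, giving 16 libraries, all of which were used. Per the labels' protocols, RNA was extracted with Trizol and a column kit, poly(A) RNA was selected, and libraries were made with a kit that does not mark strand and amplified with 9 to 10 PCR cycles, without molecular identifiers. The submitters' processing notes name STAR 2.3.0e, DESeq2 1.22.1 and the genome build mm10 without giving their roles, and state neither the annotation nor the counting program. The authors deposited 1 table of signal values per gene and library, 27179 Entrez gene IDs by 16 columns, each column matched to 1 sample. The deposited values are read counts divided by a size factor: in every column 100% of values are whole multiples of a step within 0.001, with a largest deviation of 5.89e-05. The reads recovered in this way give DESeq2's median-of-ratios size factors, from 0.868 to 1.16, equal to the reciprocals of the steps. The plan made before the data were examined had assumed whole counts and named, for normalised values, limma-trend on log2(value + 1), which was therefore used as the main test. The recovered reads were used for the depth and for alternatives with edgeR and DESeq2.

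Recovered reads per library ranged from 17056053 to 22251986, and genes with at least 1 read from 16791 to 19375. Counting error and culture differences both enter the spread between pools, and floors for genes at 0 cover counting error only, since PCR copies were not marked. Symbols and positions came from a RefSeq gene table of the same assembly (GRCm38.p6, the build of mm10) for 25275 IDs (93.0%); the other 1904 IDs, with 1.71% to 3.20% of reads, were tested under their numbers and never named. Because the libraries carry no strand, reads of overlapping genes on opposite strands cannot be told apart, and near-identical gene copies are given as uncertain.

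Values were compared as log2(value + 1) for genes at 10 or more in at least 4 libraries of the comparison, with limma-trend and a robust empirical Bayes fit, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. TGF-beta medium was compared with full medium in the 8 AKP libraries and EGF withdrawal with full medium in the 8 APT libraries, each with the line as a term. Differences between lines in a response were tested as the interaction of line and medium in the same 8 libraries, and the difference between the AKP and APT responses in all 16 libraries with a term for each line. AKP and APT were compared in full medium on the means of the 2 pools of each line, for genes at 10 or more in at least 2 lines, since the genotype belongs to the line. All p-values for genes are two-sided. Shared calls were counted beside the product of the marginal shares. Gene lists (37, written before the data were examined) were tested with limma's camera at a preset correlation of 0.01 where at least 5 members were tested, with adjustment over the lists of a comparison. Errors beside log2 changes are limma's standard errors, and errors beside normalised reads are standard deviations between libraries.

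The genes named were chosen by a rule fixed before the data were examined. For the media comparisons these are the 10 highest and 10 lowest log2 changes among called genes with the same direction in all 4 matched pairs of line and pool and a mean log2 CPM of at least 3, leaving out gene models with no established symbol. For the genotype comparison and the difference between responses they are the 5 highest and 5 lowest, and for differences between lines the 3 highest and 3 lowest. From each list described, up to 4 tested members with the smallest p were eligible, and 3 genes that the rule names are not reported here. Genes outside the rule were Areg, Tgfa and Spry1 in APT and those of the last part of the closing section, all chosen after their values were seen.

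The labels give each library a passage and a pool number, except that MTO54 in full medium at passage 14 is labelled replicate 1 with no pool. It was taken as pool 1, since its column name begins like those of the pool 1 libraries. The earlier of each line's 2 passages then lies in pool 1 and the later in pool 2, so the numbers could pair libraries. Deviations of pool 2 from pool 1 correlated across genes between the media of a line at 0.0385 for MTO54, 0.171 for MTO220, 0.174 for MTO100 and 0.127 for MTO101, and higher between some libraries of different lines (0.506 for MTO54 and MTO100 in full medium and 0.526 for MTO220 and MTO101 in full medium), with a lowest value of -0.344. The pool was therefore left out of the main fits and added as a term in an alternative. Other alternatives were edgeR's quasi-likelihood test and DESeq2's Wald test on recovered reads, TMM and library-total scaling, pseudocounts of 0.5 and 5, other filters, each line alone, pools averaged per line, a test for changes above 2-fold, and leaving out each library. Scaling, pseudocounts, edgeR with TMM on recovered reads, and the omission of the 2 EGF-withdrawal libraries with RNA under 20 ng/µl or of MTO220 were added after seeing the data.

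Both the gene test and the list test were tested on simulated data with the real genes' means and spreads. Each gene was drawn independently, so the simulated lists do not show how the list test treats correlated genes. In each comparison 67 genes were changed 1.5-fold, 67 were changed 2-fold and 66 were changed 4-fold. These are far fewer than the genes called in the real media comparisons, so the shares below need not hold for the real calls. For TGF-beta in AKP limma-trend recovered 5.97% of genes changed 1.5-fold, 49.3% at 2-fold and 98.5% at 4-fold among 13543 tested, and 11.3% of its calls were unchanged genes. For EGF withdrawal in APT these were 4.48%, 62.7% and 98.5% among 13966, with 5.98% unchanged. For AKP against APT none was recovered at any fold among 14138, so that comparison makes no calls at this size. For the difference between AKP lines 4.48% were recovered at 2-fold and 77.3% at 4-fold among 13718, and 21 unchanged genes were called (28.0% of calls), 13 of them with a group mean under 10; without such genes the share was 12.9%. For the difference between APT lines 2.99% and 72.7% were recovered among 14504, with 12.3% of calls unchanged, or 5.66% without genes of such low means. For AKP against APT responses 17.9% and 81.8% were recovered among 15203, with 23.3% unchanged, or 4.35% without genes of such low means. Of 10 simulated lists of 20 genes raised 1.5-fold, camera with the preset correlation called 10 in each comparison except AKP against APT, where it called 9, and none of 100 unchanged lists; with an estimated correlation it called 10 in the AKP and APT media comparisons and in their difference and none in the other 3. Tools were R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.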

Results

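RNA was measured by poly(A) sequencing in 16 libraries from 4 mouse tumour organoid lines (MTOs), 3-dimensional epithelial cultures grown from intestinal tumours in a basement membrane matrix. MTO54 and MTO220 had the genotype AKP, which by the field's usual reading (not spelled out in the labels) includes lesions in Apc and Trp53, and the labels give Tgfbr2 as wild type in both. MTO100 and MTO101 had the genotype APT, by the same reading lesions in Apc, Trp53 and Tgfbr2. Full medium held EGF (50 ng/ml), the BMP antagonist noggin (100 ng/ml) and galunisertib (1 µM), an inhibitor of the TGF-beta type I receptor kinase. AKP lines were also grown without galunisertib and with added TGF-beta1, and APT lines without EGF. Each of the 8 combinations of line and medium held 2 libraries, 1 from each of 2 consecutive passages, and the passages went into separate sequencing pools. Cultures in full medium were collected at day 4 and cultures in changed medium at day 7, so the change of medium and the 3 further days cannot be separated in any comparison of media. Between 17056053 and 22251986 reads per library fell on genes. Values are reads divided by the authors' size factors, called normalised reads here.

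The targeted genes were read in every library first, because they bear on the labels. Trp53 RNA (Entrez gene 22059, chromosome 11, 69580348 to 69591873, mm10) stood at 91.2 to 252 normalised reads in the 12 libraries of MTO54, MTO100 and MTO101 and at 1916 to 4207 in the 4 libraries labelled MTO220. In the full medium MTO220 held 3849 ± 507 (SD, n = 2) and MTO54 109.8 ± 17.7 (SD, n = 2). A lesion of Trp53, which the name AKP implies, was not visible as a low RNA level in the libraries labelled MTO220, and gene totals do not show whether that RNA carries a lesion. Apc RNA lay at 938 to 3956 normalised reads over the 16 libraries. Tgfbr2 RNA lay at 2349 to 5315 in the AKP libraries, 2573 to 3353 in MTO100 and 877 to 1616 in MTO101. A deleted exon or a point mutation can leave a gene's total unchanged, so these totals test neither the lesions nor the wild-type alleles, and the results below that use MTO220 as an AKP line rest on its label.

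On principal components the libraries separated by genotype and by medium. The first principal component of 15087 genes held 38.8% of the variance and the second 25.0%. The pools of a line and medium correlated across genes with Pearson r between 0.974 and 0.992; genes are not independent replicates. Mitochondrially encoded genes took 1.57% ± 0.13 of reads in AKP full medium, 2.21% ± 0.22 in AKP with TGF-beta, 1.90% ± 0.15 in APT full medium and 3.16% ± 0.64 in APT without EGF (SD, n = 4 each). RNA concentrations were 423 to 2344 ng/µl, 87.8 to 1536 ng/µl, 168 to 1586 ng/µl and 13.2 to 354 ng/µl in the same order.

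**Figure D1:**
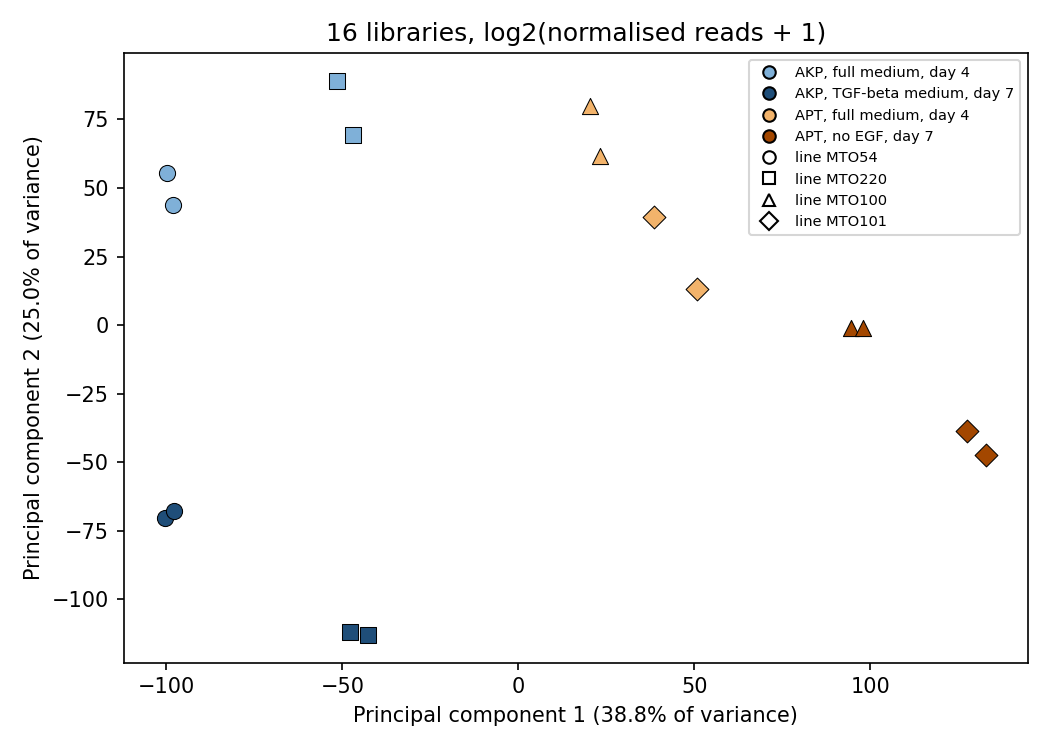
Each point is 1 library on the first and second principal components of log2(normalised reads + 1), coloured by genotype and medium, with the marker shape giving the line. All AKP libraries lie below 0 and all APT libraries above 0 on the first component (38.8% of the variance), and within each line the changed medium lies lower on the second (25.0%).

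What TGF-beta does to AKP organoids was asked by comparing 4 libraries in TGF-beta medium with 4 in full medium, with the line as a term. TGF-beta/SMAD target genes and genes of epithelial-mesenchymal transition and matrix rose, while goblet cell, cell cycle and ribosomal protein genes fell. Pmepa1 (Entrez gene 65112, chromosome 2, 173224458 to 173276731, mm10), a direct target and feedback inhibitor of TGF-beta signalling, rose from 167 ± 45.2 to 11495 ± 4282 normalised reads (SD, n = 4), a log2 change of 6.05 ± 0.26 (SE, adjusted p = 2.98e-07). Clusterin (Clu, Entrez gene 12759, chromosome 14, 65968483 to 65981548), a marker of damage-induced stem cells, rose from 609 ± 270.4 to 61872 ± 45512, a log2 change of 6.38 ± 0.28. Agr2 (Entrez gene 23795, chromosome 12, 35992925 to 36004081), a disulfide isomerase needed for mucin folding, fell from 4658 ± 3856 to 65.4 ± 28.7, a log2 change of -5.72 ± 0.59 (adjusted p = 4.24e-05). Limma-trend called 7226 of 13725 genes, 3705 higher and 3521 lower, with 2113 higher and 1641 lower by at least 2-fold. When the reads were scaled to library totals, 4262 genes were higher and 2913 lower, and this moved the median change of all genes from 0.02 to 0.14 on the log2 scale.

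Among called genes with a mean log2 CPM of at least 3 and one direction in all pairs, the other largest rises were in Piezo2 (7.56 ± 1.32), a mechanically gated ion channel, the protease inhibitor Serpine2 (7.30 ± 0.32), the laminin chain Lama3 (7.25 ± 0.74) and fibronectin (Fn1, 6.80 ± 0.70), all as log2 change ± SE. Behind them came the secreted protease Htra1 (6.43 ± 0.50), osteopontin (Spp1, 6.21 ± 0.31), the receptor phosphatase Ptprb (6.03 ± 0.25) and the troponin Tnnt2 (5.99 ± 0.51). Fn1 reached 113990 ± 105020 normalised reads, with 24027 in MTO54 and 203960 in MTO220. By the same limits the largest falls, beside Agr2, were in the calcium pump Atp2a3 (-5.77 ± 0.29), Cpn1 (-5.02 ± 0.51), galectin 4 (Lgals4, -4.17 ± 0.17), the secretory-cell transcription factor Creb3l1 (-4.08 ± 0.45) and Ern2 (-4.02 ± 0.28), an endoplasmic reticulum stress sensor of mucous cells. They were followed by Selenbp1 (-3.91 ± 0.78), the mitochondrial creatine kinase Ckmt1 (-3.89 ± 0.18), Cth (-3.89 ± 0.26), which makes cysteine, and Sord (-3.82 ± 0.38). Each of these 20 genes moved the same way in all 4 matched pairs of line and pool, with adjusted p no higher than 0.00206. With MTO54 fitted alone, Selenbp1 was not called.

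For gene lists fixed before the data were examined, the camera calls below use a preset correlation between genes of 0.01; with an estimated correlation no list was called in any comparison. In AKP, 20 of 23 tested TGF-beta/SMAD targets rose and none fell (median 1.73, camera adjusted p = 1.32e-07). Examples were Ccn2 (4.56 ± 0.28), a matricellular growth factor, the SMAD regulator Skil (2.65 ± 0.29) and the urokinase receptor Plaur (1.58 ± 0.21). All 14 tested genes of epithelial-mesenchymal transition (EMT) and matrix rose (median 1.96, adjusted p = 2.90e-06), among them the transcription factor Zeb1 from 2.49 ± 1.13 to 177 ± 116, N-cadherin (Cdh2, 3.47 ± 0.37) and Timp1 (2.90 ± 0.30). Epithelial junction genes moved both ways, 5 up and 8 down of 18 (median 0.14, adjusted p = 0.581), with Cldn4 higher (2.65 ± 0.16) and Tjp3 (-2.02 ± 0.15) and Cdh17 (-2.59 ± 0.25) lower. Targets of the YAP and TEAD regulators rose in 13 of 17 (median 1.51, adjusted p = 1.37e-05), as in Ccn1 (3.19 ± 0.33) and Ankrd1 (3.47 ± 0.37). All 4 tested fibroblast markers rose as well: Pdgfra went from 7.69 to 95.9 and Col1a1 from 3.26 to 48.8 normalised reads. Neither of the 2 tested immune markers was called, and of 3 tested endothelial markers 0 rose and 1 fell.

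Fetal-like regenerative genes rose in 10 and fell in 3 of 19 (median 0.86, adjusted p = 0.0201); mesothelin (Msln) rose (1.98 ± 0.17) and Krt4 fell (-2.66 ± 0.27). NF-kB inflammatory genes rose in 10 and fell in 3 of 19 (median 0.76, adjusted p = 0.0132), with Cxcl16 (2.08 ± 0.18) and Tnf (2.10 ± 0.30) as examples. WNT target genes went up in 11 and down in 2 of 20 (median 0.86, adjusted p = 0.0132). The WNT antagonists Dkk2 (4.02 ± 0.27) and Nkd2 (4.47 ± 0.33) and the transcription factor Sox4 (1.76 ± 0.17) rose, and the stem cell regulator Ascl2 fell from 725 ± 213 to 20.2 ± 8.52 normalised reads. Intestinal stem cell genes moved both ways, 7 up and 8 down of 21 (median -0.25, adjusted p = 0.297): Lrig1 (-3.40 ± 0.17) and Clca3b (-3.78 ± 0.25) fell and Mex3a rose (2.16 ± 0.14).

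Goblet cell and absorptive genes fell as lists. Of 10 tested goblet cell genes 9 fell and none rose (median -3.77, adjusted p = 5.52e-06), among them Galnt12 (-2.69 ± 0.20) and Bcas1 (-2.09 ± 0.16). Absorptive genes fell in 5 and rose in 1 of 8 (median -1.30, adjusted p = 0.0328), with Cdhr5 (-2.93 ± 0.30) and Ceacam1 (-2.37 ± 0.30) as examples. Of 6 tested Paneth cell genes 4 fell and 2 rose (median -2.79, adjusted p = 0.114); Reg4 went from 7264 ± 8011 to 9.12 ± 8.15 and the antimicrobial phospholipase Pla2g2a from 624 ± 475 to 9.36 ± 8.5.

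The cell cycle genes fell almost throughout: 22 of 25 S phase genes (median -1.20, adjusted p = 3.80e-08) and all 25 G2/M genes (median -1.38, adjusted p = 1.03e-09). Examples were the replication helicase subunit Mcm5 (-2.17 ± 0.23), the mitotic kinase Plk1 (-1.97 ± 0.22) and Cdc20 (-2.05 ± 0.19), which activates the anaphase-promoting complex. Cytosolic ribosomal protein genes fell in 28 of 30 (median -0.93, adjusted p = 1.32e-07) and ribosome biogenesis genes in 13 of 22 (median -0.67, adjusted p = 3.55e-05), with Rps2 (-1.17 ± 0.20) and Tcof1 (-2.02 ± 0.23) as examples. Nuclear genes of oxidative phosphorylation fell in 18 of 24 (median -0.64, adjusted p = 5.09e-05), among them Cyc1 (-1.45 ± 0.15). Mitochondrially encoded genes rose in 5 of 15 with none lower (median 0.48, adjusted p = 0.0648), and ND6 rose by 1.01 ± 0.19.

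Biosynthetic and stress programmes followed the same direction. ATF4/CHOP stress genes, which include the enzymes of serine synthesis, fell in 16 and rose in 1 of 20 (median -1.65, adjusted p = 1.60e-06): Psat1 went from 20900 ± 1623 to 2056 ± 465, with Trib3 (-3.28 ± 0.25) and Mthfd2 (-2.76 ± 0.18) also lower. Unfolded protein response genes fell in 9 and rose in 2 of 18 (median -0.36, adjusted p = 0.0164), Sdf2l1 falling (-1.59 ± 0.17) and Dnajb9 rising (1.11 ± 0.20). Hypoxia and glycolysis genes fell in 15 and rose in 2 of 24 (median -1.29, adjusted p = 6.28e-04), with Ldha (-1.74 ± 0.23) and Eno1 (-1.50 ± 0.21) lower. Cholesterol synthesis genes fell in 13 of 21 (median -0.51, adjusted p = 3.55e-05). EGFR/ERK targets were not called as a list (median 0.13, adjusted p = 0.477), though 6 of 23 rose, Ccnd1 (0.92 ± 0.16) and Hbegf (1.80 ± 0.34) among them. Adjusted over the list alone, the SMAD targets counted 22 higher, YAP targets 14 higher, NF-kB genes 12 higher, S phase genes 23 lower, hypoxia and glycolysis genes 16 lower and ribosome biogenesis genes 14 lower, and the counts of the other lists given so far for AKP did not change. Of the lists not called, BMP targets had 4 higher and 2 lower of 10, TGF-beta pathway components 6 higher and none lower of 11, and MHC genes 4 higher and 4 lower of 9. The genes of cell death in the BCL2 family had 8 higher and 2 lower of 17, and p53 targets 6 higher and 5 lower of 20 (adjusted over the list alone, 3 and 6 lower). For the junction, tuft cell and p53 target lists the median, the mean and the test differed in sign.

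The call counts rested unequally on the lines: MTO54 alone gave 3782 genes and MTO220 alone 8942. Averaging the pools and pairing by line left 2441, and 1280 genes passed a test for changes above 2-fold. Without a term for the line, Cdh2, Clca3b and Id1 were not called, nor was Dnajb9 with MTO54 alone, nor Dnajb9, Ccnd1 and Hbegf with averaged pools.

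**Figure D2:**
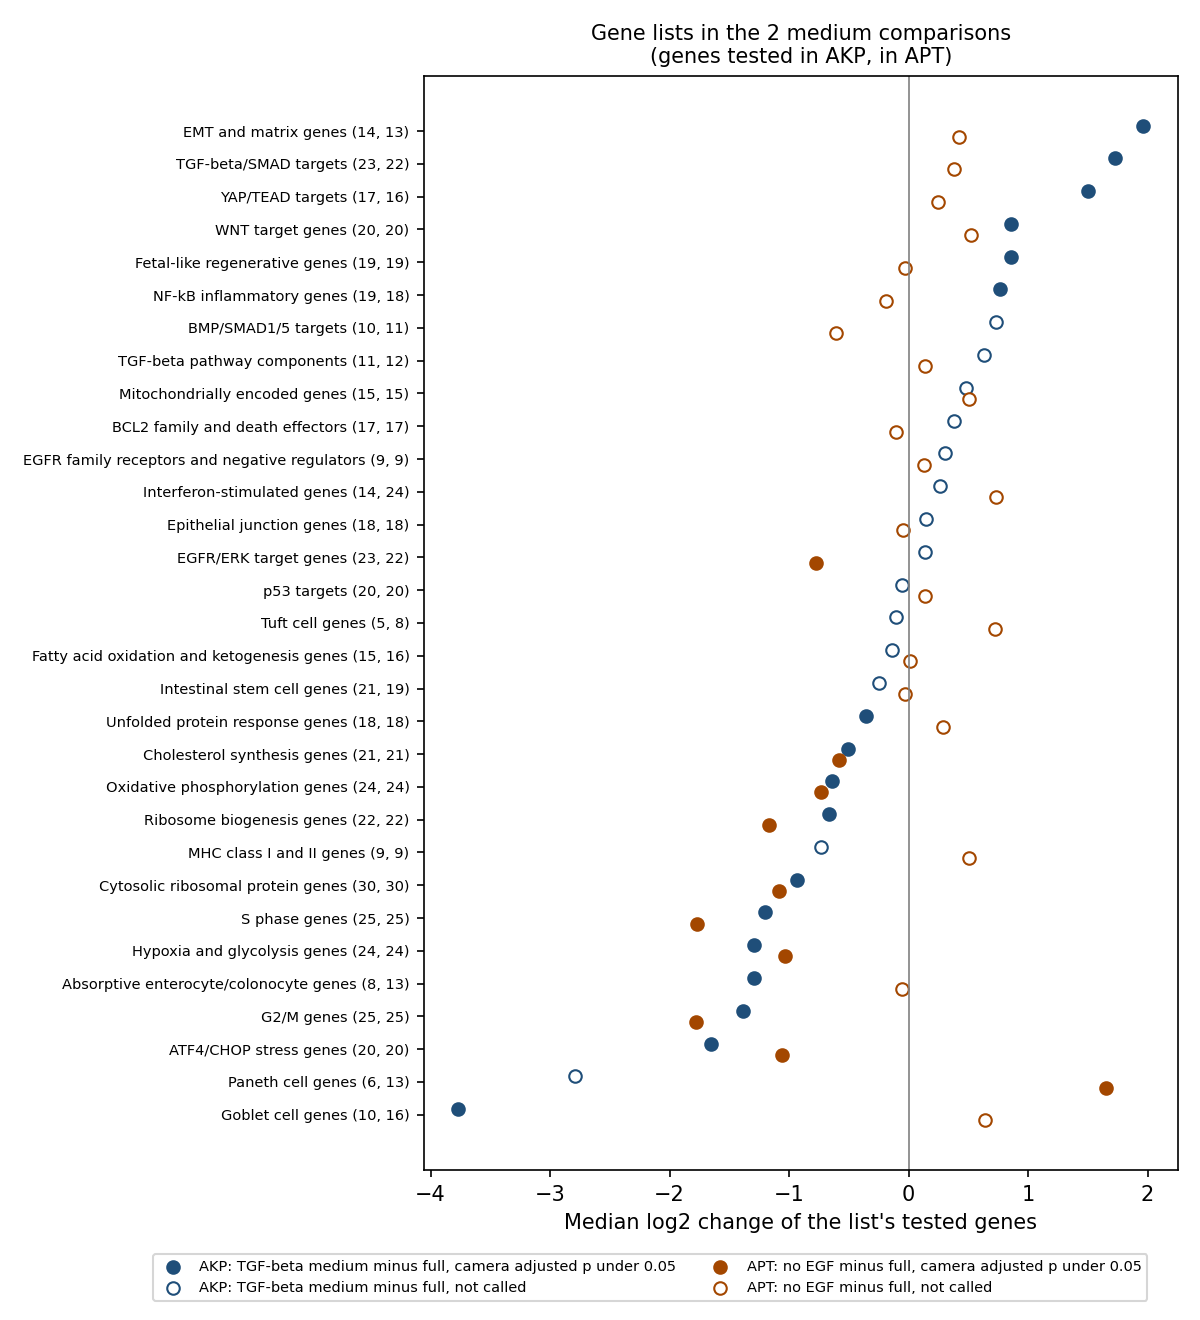
Each row is a gene list, with the median log2 change of its tested genes in AKP (TGF-beta minus full medium, blue) and in APT (no EGF minus full medium, brown); filled points were called by camera with a preset correlation. The cell cycle, ribosome, glycolysis, cholesterol and ATF4/CHOP lists lie below 0 in both comparisons, while the EMT and SMAD target medians reach 1.96 and 1.73 in AKP against 0.42 and 0.38 in APT.

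What EGF withdrawal does to APT organoids was asked in the same way with 4 libraries in each medium. EGFR/ERK target genes fell on balance, cell cycle genes fell, and genes of Paneth and enteroendocrine cells rose. Etv4 (Entrez gene 18612, chromosome 11, 101769747 to 101785310, mm10), a transcription factor induced by ERK, fell from 1360 ± 495 to 91 ± 40.2 normalised reads (SD, n = 4), a log2 change of -3.93 ± 0.33 (SE, adjusted p = 1.61e-05). Chromogranin A (Chga, Entrez gene 12652, chromosome 12, 102554941 to 102565027), a granule protein of enteroendocrine cells, rose from 40.1 ± 14.6 to 1008 ± 406, a log2 change of 4.62 ± 0.27 (adjusted p = 2.40e-06). Lysozyme (Lyz1, Entrez gene 17110, chromosome 10, 117287795 to 117292868), an antibacterial enzyme of Paneth cells, rose from 199 ± 223 to 1601 ± 1265, though reads may be shared with its near-identical copy Lyz2. Limma-trend called 6969 of 14373 genes, 3849 higher and 3120 lower, with 2239 higher and 1372 lower by at least 2-fold. When the reads were scaled to library totals, 5139 genes were higher and 2086 lower, and the median change of all genes moved from 0.08 to 0.31 on the log2 scale.

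With a mean log2 CPM of at least 3, the other largest rises were in the kinase gene Srpk3 (5.93 ± 0.29), the surface glycoprotein Gp2 (4.74 ± 0.25), the retrotransposon-derived Rtl5 (4.50 ± 0.30) and Cd200r2 (4.34 ± 0.37). Below these stood the nuclear non-coding RNA Malat1 (4.08 ± 0.47), the cytokine Il18 (3.97 ± 0.22), Col23a1 (3.94 ± 0.35) and Podn (3.90 ± 0.22). The call of Malat1 was lost when MTO100 was fitted alone. Of the 10 largest falls by the same limit, 8 were histone H2A genes (H2ac7, H2ac11, H2ac12, H2ac13, H2ac15, H2ac22, H2ac23 and H2ac24), with log2 changes from -3.63 to -3.47; these copies are near identical and their reads cannot be assigned with certainty. Ly6c2 also fell (-3.39 ± 0.35), with the same reservation for its close relative Ly6c1. All 20 genes moved the same way in each of the 4 matched pairs.

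EGFR/ERK targets fell in 11 and rose in 3 of 22 (median -0.78, camera adjusted p = 0.00611; 11 lower and 5 higher adjusted over the list alone). Cyclin D1 (Ccnd1, -1.23 ± 0.16), Myc (-0.94 ± 0.15) and Epha2 (-1.10 ± 0.18) fell. The members that rose, named after their values were seen, were Areg (1.21 ± 0.25) and Tgfa (1.42 ± 0.29), which encode EGFR ligands, and the ERK inhibitor Spry1 (0.67 ± 0.23). EdgeR with TMM and DESeq2 did not call Spry1, edgeR with the size factors of DESeq2 did, and limma-trend did not without the pool 1 library of MTO100 or MTO101 in full medium or without either EGF-withdrawal library of MTO101. It was also not called with MTO100 alone, with averaged pools, or without the 2 pool 2 EGF-withdrawal libraries. All 25 S phase genes (median -1.77, adjusted p = 1.49e-15) and all 25 G2/M genes fell (median -1.78, adjusted p = 5.48e-16), with Rrm2 (-2.25 ± 0.19), Mcm5 (-2.64 ± 0.23), Aurka (-2.10 ± 0.16) and Ccnb1 (-2.31 ± 0.20) as examples.

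Paneth cell genes rose in 9 of 13 and none fell (median 1.65, adjusted p = 6.63e-04; 10 adjusted over the list alone), including Pla2g2a from 665 ± 559.5 to 3310 ± 2429, Itln1 (1.73 ± 0.21) and the defensin Defa22 (4.61 ± 0.56), 1 of a family with similar sequences. Enteroendocrine genes rose in 7 of 9 and none fell (median 1.99, adjusted p = 0.0019), with Chgb (3.65 ± 0.36) and the transcription factor Insm1 (2.65 ± 0.34) beside Chga. Tuft cell genes rose in 4 of 8 (median 0.72, adjusted p = 0.086), with Trpm5 at 11.2 ± 7.48 and 95.2 ± 12.1 and the master regulator Pou2f3 at 13.7 ± 7.91 and 72.5 ± 16.5. Goblet cell genes rose in 6 and fell in 3 of 16 (median 0.64, adjusted p = 0.366), and Bcas1 (1.52 ± 0.21) and the mucin Muc2 (3.54 ± 0.50) rose. Intestinal stem cell genes moved both ways, 4 up and 4 down of 19 (median -0.03, adjusted p = 0.7): Smoc2 rose from 8554 ± 3417 to 32041 ± 6146, and Igfbp4 (-2.33 ± 0.17) and Ascl2 (-1.55 ± 0.19) fell.

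Ribosomal protein genes fell in 28 of 30 (median -1.08, adjusted p = 9.35e-09) and ribosome biogenesis genes in 21 of 22 (median -1.16, adjusted p = 9.13e-10; 22 adjusted over the list alone), with Rps2 (-1.50 ± 0.25) and Tcof1 (-1.73 ± 0.21) as examples. Oxidative phosphorylation genes fell in 16 of 24 (median -0.74, adjusted p = 1.90e-05; 20 adjusted over the list alone), Cyc1 (-1.31 ± 0.17) among them. Hypoxia and glycolysis genes fell in 13 of 24 (median -1.04, adjusted p = 6.33e-05), including Ldha from 46695 ± 22232 to 7679 ± 778. Cholesterol synthesis genes fell in 13 of 21 (median -0.58, adjusted p = 3.13e-04), such as Fdps (-1.53 ± 0.23). ATF4/CHOP stress genes fell in 10 and rose in 1 of 20 (median -1.06, adjusted p = 0.00143; 11 lower adjusted over the list alone), with the serine pathway enzymes Shmt2 (-2.27 ± 0.17), Psat1 (-1.91 ± 0.19) and Phgdh (-1.77 ± 0.20) lower. Mitochondrially encoded genes rose in 6 of 15 with none lower (median 0.51, adjusted p = 0.107); ND4 went from 14892 ± 1057 to 36248 ± 10318. Interferon-stimulated genes rose in 12 and fell in 3 of 24 without a call as a list (median 0.74, adjusted p = 0.0807; 13 higher adjusted over the list alone), with Ddx58 (1.21 ± 0.17) as an example. Of markers of other cell types, 3 of 4 tested for fibroblasts rose and 0 fell, 2 rose and 1 fell of 4 for immune cells, and 2 rose and 0 fell of 5 for endothelium. Among them Pdgfra of fibroblasts went from 53.3 to 269 and Vwf of endothelium from 398 to 1016 normalised reads. Of the lists not called, SMAD targets had 6 higher and 4 lower of 22, EMT and matrix genes 6 higher and 3 lower of 13 (4 lower adjusted over the list alone), and WNT targets 7 higher and 4 lower of 20. Genes of EGFR family receptors and their negative regulators had 2 higher and none lower of 9. Adjusted over the list alone, the counts of the other lists given for APT did not change. For the absorptive, BCL2 family, NF-kB and fatty acid oxidation lists the median, the mean and the test differed in sign.

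The 2 EGF-withdrawal libraries of pool 2 came from RNA at 14.6 and 13.2 ng/µl, the lowest of the series, and without them 3804 genes were called. Averaging pools and pairing by line left 4438 genes, and 851 passed a test for changes above 2-fold. Without a term for the line, Ascl2, Epha2, Areg, Id1, Pdgfra and Spry1 were not called.

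**Figure D3:**
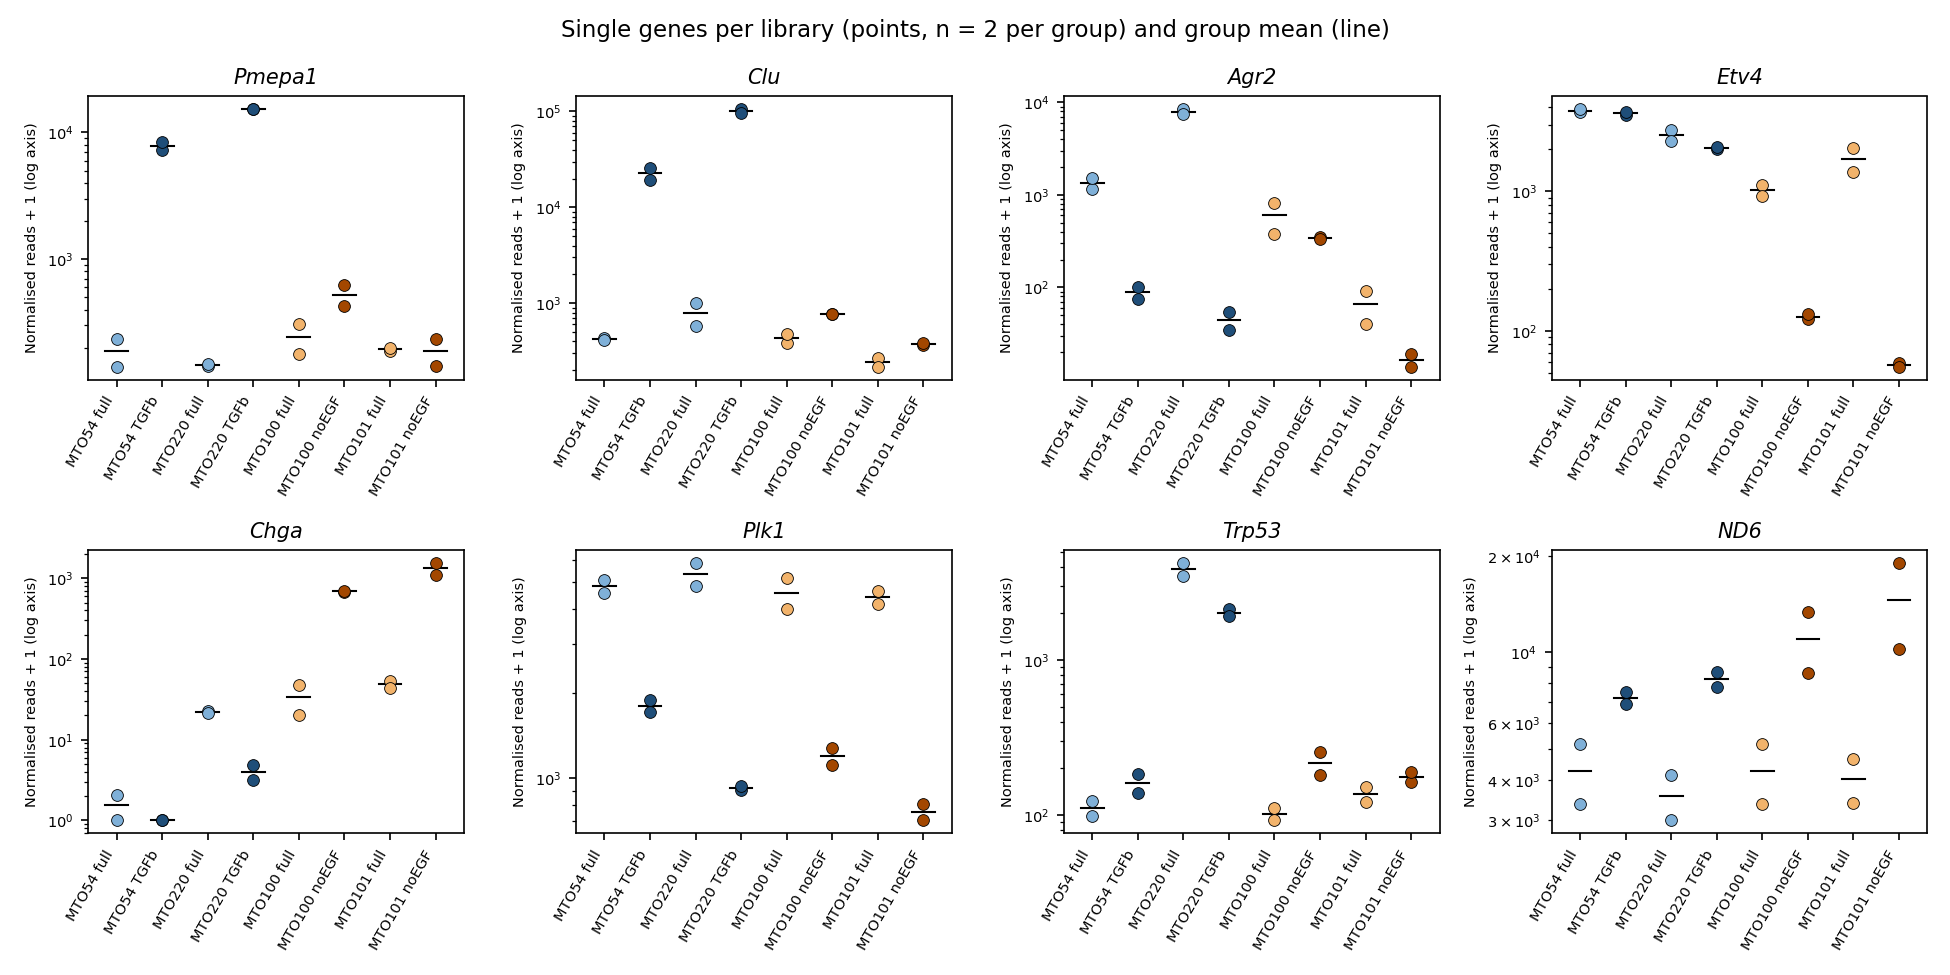
Each panel shows 1 gene, with normalised reads plus 1 on a log axis, a point per library and a line at the mean of the 2 libraries of each line and medium. Pmepa1 and Clu rose in both AKP lines with TGF-beta, Etv4 fell in both APT lines without EGF, Plk1 fell and ND6 rose in all 4 lines, and Trp53 was at 1916 or more in MTO220 alone.

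The changes in the AKP and APT lines were set side by side to see what was common and what differed. Of 13287 genes tested in both comparisons, 1797 rose in both and 1943 fell in both, where independent lists would share 841.8 and 804.9. The balance depended on the scaling: 2452 rose and 1351 fell in both under library-total scaling, and 1570 and 2194 under TMM. Opposite calls numbered 161 (higher with TGF-beta, lower without EGF) and 206 (the reverse), where independence would give 804.5 and 842.3. The log2 changes correlated across genes with Pearson r = 0.51 and Spearman rho = 0.57; genes are not independent replicates. No library belonged to both comparisons, but both ran from day 4 to day 7. With MTO54 alone standing for AKP the shared calls were 1899, and without the low-RNA pool 2 libraries 2385, against 3740 in the full data.

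**Figure D4:**
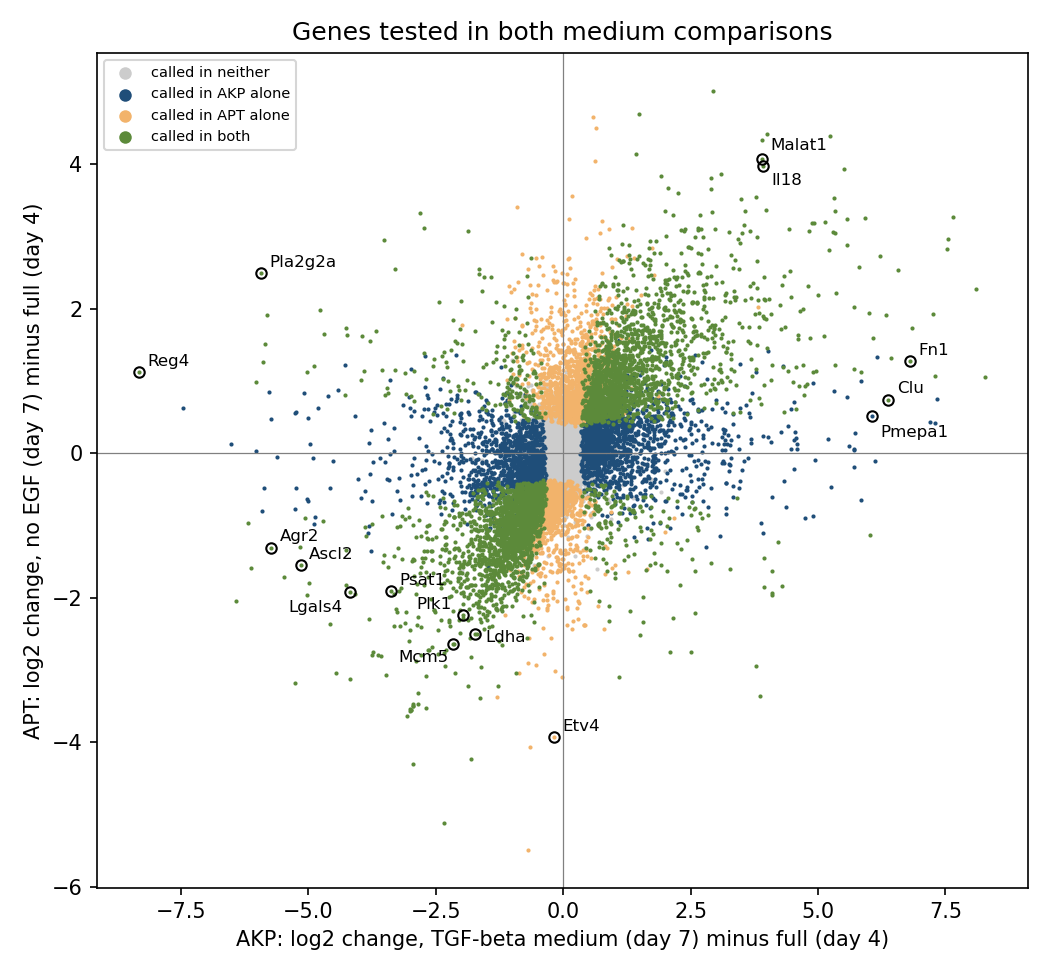
Each point is 1 of 13287 genes, with its log2 change in AKP (TGF-beta minus full medium) on the x axis and in APT (no EGF minus full medium) on the y axis, coloured by which comparison called it. Cell cycle genes such as Plk1 and Mcm5 lie low on both axes, Pmepa1 and Clu far right near the horizontal axis, Etv4 far down near the vertical axis, and Pla2g2a and Reg4 low in AKP and high in APT.

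A test of the difference between the changes (AKP minus APT, all 16 libraries in 1 fit) called 3343 of 15087 genes, 1582 with a higher and 1761 with a lower change in AKP. Under library-total scaling 1265 were higher and 1988 lower, and the median of all genes moved to -0.10. Libraries, not lines, were the replicates in this fit, although the genotype belongs to the line. Its p-values therefore rest mostly on the spread between passages of a line, and no fit with lines as replicates was run. Among genes with a mean log2 CPM of at least 3 the highest were Clu (5.64 ± 0.34), Pmepa1 (5.54 ± 0.44), Fn1 (5.53 ± 0.88), Lama3 (5.32 ± 0.95) and moesin (Msn, 5.25 ± 0.50). By the same limit the lowest were the matrix proteoglycan Prelp (-7.01 ± 0.49), Rdh9 (-6.76 ± 0.65), Atp2a3 (-6.61 ± 0.65), the mucus protein Fcgbp (-6.47 ± 0.89) and the zinc transporter Slc30a2 (-6.14 ± 0.64). SMAD targets had a higher change in AKP in 14 of 23 (median 1.52, camera adjusted p = 1.16e-08; 16 adjusted over the list alone), as in Ccn2 (4.26 ± 0.41). EGFR/ERK targets had a higher change in AKP in 12 and a lower one in 1 of 23 (median 1.14, adjusted p = 2.12e-04), with Etv4 at 3.75 ± 0.39 and Ccnd1 at 2.15 ± 0.21. The BMP target Id1 rose in AKP (1.20 ± 0.17) and fell in APT (-1.21 ± 0.23), a difference of 2.41 ± 0.30. Lower changes in AKP covered 15 of 17 goblet cell genes (median -4.42, adjusted p = 9.20e-12; 16 adjusted over the list alone). They also covered 9 of 14 Paneth cell genes (median -5.56, adjusted p = 8.27e-06; 10 adjusted over the list alone) and 10 of 13 enteroendocrine genes (median -4.67, adjusted p = 1.42e-04). Pla2g2a differed by -8.41 ± 0.43, Chga by -6.14 ± 0.58 and Bcas1 by -3.61 ± 0.26. Fewer goblet, Paneth and enteroendocrine cell genes passed the filter in AKP alone than here. The enteroendocrine genes that passed in AKP were too few for a list test there. Among them Cpe rose in all 4 AKP pairs, and Reg4 and Sct fell in all 4. For Chga the difference came mainly from the rise in APT: its log2 changes in the pairs ran from 3.85 to 5.13 there and from -2.86 to 0 in AKP. Cell cycle genes fell in both, and the fall was smaller in AKP for 6 of 25 S phase genes (median 0.62, adjusted p = 2.31e-04), while Psat1 fell further in AKP (-1.47 ± 0.25). Of the 3343 genes, 1041 had a mean under 10 normalised reads in at least 1 combination of line and medium, where log2(value + 1) compresses a change and can make equal fold changes look unequal; edgeR on recovered reads called 3216. Leaving out the pool 2 EGF-withdrawal libraries gave 2133 genes and leaving out MTO220 gave 2073.

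To see how the genotypes differ before any challenge, AKP and APT lines were compared in full medium with the line as the replicate, 2 against 2. The ATF4 programme stood higher in AKP: Trib3 was at 2302 and 3222 normalised reads in the AKP lines and 321 and 317 in the APT lines, a log2 difference of 3.09 ± 0.23 with adjusted p = 0.185. Atf4 itself differed by 1.67 ± 0.17 and Chac1, a glutathione-degrading enzyme, by 2.32 ± 0.28. As a list, ATF4/CHOP stress genes were higher in AKP (median 1.51, camera adjusted p = 5.33e-17), with none of 20 passing over all genes and 16 adjusted over the list alone. EGFR/ERK targets were higher in AKP too (median 1.08, adjusted p = 3.70e-09; 4 of 23 adjusted over the list alone), with differences of 1.80 ± 0.32 for Dusp5, 2.32 ± 0.42 for Fosl1 and 3.16 ± 0.61 for Areg. Interferon-stimulated genes had a lower median in AKP (-1.78, camera adjusted p = 2.63e-09), though 0 of 23 genes passed even when adjusted over the list alone. Oasl2 stood at 5.66 and 21.4 in the AKP lines against 248 and 257 in the APT lines. Higher medians in AKP were also called for unfolded protein response (0.50), hypoxia and glycolysis (0.45), fetal-like (0.49), SMAD target (0.50), cholesterol synthesis (0.26) and ribosome biogenesis (0.21) genes, and a lower one for oxidative phosphorylation (-0.22). With an estimated correlation between genes, none of these lists was called. No single gene of 13898 passed limma-trend after adjustment, 1437 had an unadjusted p under 0.05, edgeR called 0, and DESeq2's Wald test called 797. On simulated data of this size limma-trend recovered none of the changed genes even at 4-fold, so this count does not bear on whether the genotypes differ; with the 8 libraries as replicates, which counts each line more than once, 927 genes were called.

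Whether the lines of 1 genotype respond alike was tested with the interaction of line and medium. The libraries labelled MTO220 had the larger response of SMAD targets: 12 of 23 were called with a higher change than in MTO54 and none with a lower one (median difference 1.61, camera adjusted p = 3.34e-12; 17 adjusted over the list alone). The integrin Itga5 went from 228 to 709.9 in MTO54 and from 103 to 3052 in MTO220, a difference of 3.21 ± 0.33, and Fn1 (4.21 ± 0.49) differed the same way. Among genes with a mean log2 CPM of at least 3 the largest differences were in the transcription factor Onecut2 (8.27 ± 0.33), Piezo2 (7.51 ± 0.37) and the basal keratin Krt14 (5.11 ± 0.50) on the higher side and in Agr2 (-3.61 ± 0.37), Maoa (-2.97 ± 0.41) and Acsm3 (-2.86 ± 0.46) on the lower. Onecut2 stood at 1226 and 969 in MTO54 and rose from 14.7 to 3927 in MTO220. G2/M genes fell further in MTO220 in 16 of 25 (median -1.09, adjusted p = 4.46e-14; 20 adjusted over the list alone), such as Cdca3 (-1.94 ± 0.28), and goblet cell genes in 7 of 10 (median -2.74, adjusted p = 9.22e-07), with Creb3l1 (-2.66 ± 0.35) and Fcgbp (-2.85 ± 0.40). In all, 1126 of 13725 genes were called, 753 with a higher and 373 with a lower change in MTO220, 208 of them with a group mean under 10. The size of this set rested on single libraries: it was 2384 without the pool 1 library of MTO54 in full medium and 629 without that of MTO220 in full medium. It was 476 or 538 without the pool 1 or pool 2 library of MTO54 with TGF-beta, and 343 or 389 without the pool 1 or pool 2 library of MTO220 with TGF-beta.

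Between the APT lines, the response to EGF withdrawal differed for 337 of 14373 genes, 156 higher and 181 lower in MTO101, or 80 higher and 150 lower under library-total scaling, which moved the median of all genes to -0.12. With a mean log2 CPM of at least 3, the highest were Fer1l4 (3.96 ± 0.34), the purine enzyme Xdh (3.92 ± 0.38) and Trim29 (3.68 ± 0.33), and the lowest syndecan 2 (Sdc2, -3.94 ± 0.42), nestin (Nes, -3.62 ± 0.32) and Dkk2 (-3.60 ± 0.68). The WNT-responsive transcription factor Sp5 fell further in MTO101 (-2.81 ± 0.29), from 4758 to 449 against 1353 to 898 in MTO100. S phase (median -0.75) and G2/M genes (median -0.73) had lower changes in MTO101 as lists (camera adjusted p = 4.53e-07 and 4.38e-08), with none of the 25 tested members of either list passing, over all genes or adjusted over the list alone. Here too single libraries decided the count: it was 982 without the pool 2 library of MTO101 in full medium and 187 or 176 without the pool 1 or pool 2 library of MTO100 in full medium. It was 94 or 102 without the pool 1 or pool 2 library of MTO100 without EGF and 80 or 94 without those of MTO101 without EGF. Without any 1 of these 4 EGF-withdrawal libraries Dkk2 was not called, and without both from pool 2 the count was 1.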

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

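The tests of splits of the libraries were planned, and the tests of single explanations were chosen after the result each one explains had been seen. The results gathered here differ between 2 groups by a direct test of the difference, an interaction in limma-trend.

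AKP organoids with TGF-beta and APT organoids without EGF differed in their response at 3343 genes and 15 lists, with libraries rather than lines as replicates. The AKP response was higher for Clu (5.64 on the log2 scale), Pmepa1 (5.54), Fn1 (5.53), Lama3 (5.32), Msn (5.25), Ccn2 (4.26), Etv4 (3.75), Id1 (2.41) and Ccnd1 (2.15). It was lower for Pla2g2a (-8.41), Prelp (-7.01), Rdh9 (-6.76), Atp2a3 (-6.61), Fcgbp (-6.47), Chga (-6.14), Slc30a2 (-6.14), Bcas1 (-3.61) and Psat1 (-1.47). The lines MTO100 and MTO101 differed in their response to EGF withdrawal at 337 genes and 9 lists, with higher values in MTO101 for Fer1l4 (3.96), Xdh (3.92) and Trim29 (3.68) and lower ones for Sdc2 (-3.94), Nes (-3.62), Dkk2 (-3.60) and Sp5 (-2.81).

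The TGF-beta response differed between MTO220 and MTO54 at 1126 genes, 753 with a higher and 373 with a lower change in MTO220, and at 13 lists. The change was higher in MTO220 for Onecut2 (8.27), Piezo2 (7.51), Krt14 (5.11), Fn1 (4.21) and Itga5 (3.21), and lower for Agr2 (-3.61), Maoa (-2.97), Acsm3 (-2.86), Fcgbp (-2.85), Creb3l1 (-2.66) and Cdca3 (-1.94). The pattern weighed is the larger response of the SMAD targets in MTO220, and these accounts of it are argued against by the tables. The first account is a share of MTO54 cells that changed neither with the medium nor with the 3 further days. The weaker rise of the SMAD targets would need 68.8% of MTO54 cells to be of this kind. No gene could then fall below that share of its full-medium level. Of 6971 genes at 500 or more normalised reads in full medium, 30 fell under 10%, the 10th lowest to 4.21%. Cells that ignored TGF-beta but changed over the 3 further days are not covered, since medium and day cannot be separated. A sequencing pool is argued against because the median difference over the SMAD targets was 1.41 in pool 1 and 1.68 in pool 2. A lower starting level in MTO220 does not account for all of it: in TGF-beta medium itself MTO220 stood higher by a median of 0.963, in 20 of 23 targets, while in full medium the median difference was -0.361. RNA of the cultures with TGF-beta was at 280 and 87.8 ng/µl in MTO220 and at 1536 and 850 ng/µl in MTO54. The passages were 10 and 11 in MTO220 and 14 and 15 in MTO54. Neither RNA amount nor passage was tested as a cause of the larger response. A biological difference between the tumours, Trp53 status among them, may underlie the larger response, but each line is a single tumour and no test here separates that from any other property of the line.

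Trp53 RNA in MTO220 was another pattern. A single wrong library is argued against, since the lowest of the 4 MTO220 values was 7.61 times the highest of the other 12 libraries so all 4 share the high level. An exchange of the whole line with an APT line, read as carrying a Tgfbr2 lesion, is argued against by the SMAD targets. Of 23 tested, 22 rose with TGF-beta in both MTO54 and MTO220. An exchange with MTO54, or another wrong label on all 4 libraries, would give the same values and was not tested. Stromal, immune or endothelial cells with an intact gene are argued against too: 33 of their markers summed to 1034 normalised reads in MTO220 and 1615 in MTO54 in full medium, a difference of -15.5% of that in Trp53. The sums rest largely on few genes, Acta2 and Tagln making up 66.3% of that in MTO220. Col1a1, Col1a2 and Col3a1 together stood at 7.18 there, against 3849 for Trp53. Whether p53 is functional there stays open. In full medium 19 tested p53 targets differed between MTO220 and MTO54 by a median of -0.0197 on the log2 scale, 9 higher and 10 lower, and members that go both ways decide nothing. A point mutation that leaves the RNA in place may be the reason, and sequence reads, not analysed here, would be needed to tell.

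The third pattern is the part that both responses share, 3740 genes called in the same direction. Low RNA in the pool 2 cultures without EGF is argued against as its source, since without them the responses correlated across genes at 0.504 against 0.511 with them. With fewer libraries the shared calls were 2385. The pool 1 library of MTO100 without EGF, at 48.2 ng/µl, was kept, so low RNA in the remaining cultures is not covered. The 3 further days in culture could equally underlie the shared part. There were 0 libraries in full medium at day 7, so growth stage and change of medium cannot be told apart for these genes.

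Chance was tested with other splits of the same libraries. For TGF-beta in AKP and for EGF withdrawal in APT, 1 of 34 splits that could be fitted called as many genes as the real one, the real one itself. The counts were 7226 and 6969 genes against at most 0 in any other split, a share under 0.05 among splits of any kind. Many of these splits exchange libraries between lines, which are not alike, so this share does not by itself exclude chance. The splits that parted all 4 pairs of line and pool numbered 8 in each, the real one included. These are too few for a share under 0.05 on their own. The others called 0 genes, as did the split by pool. In both comparisons the other splits were fitted without a term for the medium, whose effect then stayed in the spread between libraries. Low counts were therefore likely in advance, and the 0 for the split by pool says nothing about a pool effect. For the difference between the AKP and APT responses only 3 splits of the lines exist, too few for a share under 0.05, with 3343 genes in the real one and at most 37 in the others.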

How the results depend on the processing

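The alternatives were planned, except edgeR with TMM on recovered reads, other scalings for limma-trend, other pseudocounts for the numbers of genes called, a filter on means in 3 comparisons, shared calls with 1 AKP line alone and the omission of low-RNA libraries or of MTO220, which were chosen after seeing the data. No named gene changed direction under any alternative run. More genes were called lower than higher under TMM scaling in AKP (3783 and 3490) and APT (3506 and 3466), the reverse of the balance under the authors' size factors. Mitochondrially encoded genes were called between genotypes under library-total scaling (adjusted p = 0.043), absorptive genes no longer between AKP lines (0.0528), and BMP targets between AKP lines under TMM (0.0469). Counts moved by more than 1.5 times in these cases, and the cause was tested in none of them beyond what the setting itself removes. For TGF-beta in AKP (7226 genes), pools averaged and paired by line gave 2441, MTO54 alone 3782 and a test for changes above 2-fold 1280. For EGF withdrawal in APT (6969), pools averaged gave 4438, the 2-fold test 851 and omission of the low-RNA pool 2 libraries 3804. Leaving out each library in turn gave 5435 to 7734 genes in AKP and 5000 to 7194 in APT, within 1.5 times of the full counts. For AKP against APT in full medium (0), DESeq2's Wald test gave 797, the 8 libraries as replicates 927, the same with the pool as block 917, and voom with a correlation within lines 443. For the difference between AKP lines (1126), leaving out each library gave 343 to 2384. For that between APT lines (337), DESeq2 gave 616, leaving out each library gave 80 to 982, and omission of the low-RNA libraries gave 1. For the difference between responses (3343), omission of the low-RNA libraries gave 2133 and of MTO220 2073. The 3740 shared calls became 2385 without the low-RNA libraries and 1899 with MTO54 alone. List calls (17 in AKP, 11 in APT, 10 between genotypes, 13 and 9 between lines and 15 between responses) fell to 0 with an estimated correlation in each. The same setting called simulated lists in the media comparisons, but the simulated genes varied independently. Those simulated calls therefore say nothing about lists of correlated genes. The pool as a block changed no other call by more than 1.5 times. Of 67 genes named for TGF-beta in AKP and 57 for EGF withdrawal in APT, 12 and 18 lost their call in some setting, 9 and 17 of them under the 2-fold test. All 7 genes named between APT lines lost it without the low-RNA libraries, the 11 between AKP lines and 18 between responses in none, and the 7 between genotypes, not called, were called by DESeq2. A library left alone in its line and medium was assumed to vary like the others.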

Other observations

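These values were chosen after the data were seen. In full medium Muc2, the main gel-forming mucin of goblet cells, stood at 2258 ± 1428 normalised reads in MTO220 and 5.61 ± 3.3 in MTO54 (SD, n = 2), and Reg4, of deep crypt secretory cells, at 14176 ± 1196 and 352 ± 5.6. With TGF-beta, Muc2 stood at 12.3 ± 8.2 and Reg4 at 16.1 ± 1.44 in MTO220. Peptide YY (Pyy), a hormone of enteroendocrine cells, was at 2459 and 1569 in the 2 libraries of MTO220 with TGF-beta and at no more than 1.15 in any other library.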
